A study of Mus musculus with 6 samples.

How the data were processed

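Epithelial cells were isolated from the dissected small intestine of mice with collagen-induced arthritis, and total RNA was sequenced on an Illumina protocol, per the labels' protocols. The 6 libraries were put in 2 groups of 3 by their genotype label, and replicate numbers, given in accession order, only name libraries. Nothing in the labels says that the libraries of a group came from separate mice. Levels of Xist and Eif2s3y set control library 1 apart from 2 and knockout library 3 apart from 1 and 2 by sex, so neither group can be repeats of 1 mouse, but for knockout libraries 1 and 2 this does not tell.

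The authors used cutadapt 1.18, FastQC 0.11.8, STAR 2.6.1c, SAMtools 1.8 and Subread 1.6.1 with the GRCm38 (mm10) build, per the submitters' processing notes. How these were set, including strand and reads that map to several places, is not given in the sources used here, so overlapping genes, antisense genes and near-identical gene copies are uncertain. The authors deposited raw read counts per gene for 55298 Ensembl genes, with totals from 28937122 to 38454620 per library. They also deposited a normalised signal, which equals the read counts divided by DESeq2 size factors recomputed from them, and regularised log2 values. The counts were used for all tests, the signal to recover the size factors, and the log2 values for a principal component analysis, whose first component held 75.6% of the variance.

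Gene names, positions, lengths and GC content came from GENCODE M21 on GRCm38, in which 55117 identifiers matched without their version suffix and 54550 with it. Length and GC content were medians over the annotated transcripts of a gene, which can differ from those of the transcript expressed. Genes on the mitochondrial chromosome were not analysed here. Library pairs were compared by a chi-square test of their counts: every pair, within and between groups, differed by at least 95.7 per degree of freedom, and none was treated as one library sequenced again.

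Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, after filterByExpr (minimum count 10, minimum total 15), which kept 15143 genes and between 99.89% and 99.95% of each library's reads. Libraries were scaled by TMM, whose factors were 0.75, 0.87 and 0.92 in the control libraries and 1.27, 1.17 and 1.12 in those labelled knockout. The robust quasi-likelihood test compared the groups, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-scaled. Gene lists, 37 in number, were fixed before the data were examined and tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which left 34. The list of mitochondrially encoded genes was not analysed here.

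In the GC content and length correction, each library's deviation in log2 CPM (prior count 2) from the mean of the libraries was fitted by natural splines of transcript GC content (6 degrees of freedom) and log2 length (5), and the fit was used as an offset. It left 15135 genes with a GC value. It removes any true difference between the groups that follows GC content or length, so the corrected changes can be too small as well as the uncorrected ones too large. The correction can also enlarge or reverse a change.

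The steps were tested on simulated data drawn from the real libraries' means and sizes, with 2-fold and 4-fold changes put in. With no GC trend, the uncorrected fit found 21% of the 2-fold and 95% of the 4-fold changes among 14788 genes and called 9 unchanged genes. With the libraries' own GC and length trends added, it called 7205 unchanged genes of 14818 tested, and the corrected fit called 7 of 14811 while finding 20% of the 2-fold and 87% of the 4-fold changes. The added trends came from the same spline fit that the correction removes, so trends of another shape were not tested. They also used the same GC content and length values, so errors in these were not tested.

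The genes named were drawn from Epas1, the 10 largest changes in each direction and the 5 smallest p in each direction among genes past the threshold with a mean of at least 2 CPM, a symbol that is not a predicted-gene name and groups that do not overlap. To these were added at most 4 members past the threshold from each list, the members of the iron list and Cldn15. The rule was fixed before the data were examined. Some genes that it allows are not reported here. Within the list members it allows, those that kept their call after correction were preferred, a choice made after seeing the data. Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, no robust estimation, no filter (at least 1 read), a stricter filter (1 CPM in 3 libraries), removal of the 20 most abundant genes, other thresholds, camera with an estimated correlation, fry, and each library left out. The GC content and length correction, the correction for GC content alone, total count scaling and each library's GC slope as a covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.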

Results

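RNA was sequenced from epithelial cells of the mouse small intestine in collagen-induced arthritis, a model in which immunisation with collagen gives joint inflammation. Of the 6 libraries, 3 carry the genotype label HIF2α +/- ΔIEC, described as an intestinal knockout, and 3 the label HIF2α +/- F/F of littermate controls. What the +/- in both labels stands for is not given in the sources used here. HIF2α, encoded by Epas1, is a subunit of a transcription factor that is stabilised at low oxygen. The libraries held between 28937122 and 38454620 counted reads, and 27194 of the 55298 annotated genes had at least 1 read. The median count of a tested gene in a library was 444 reads. The comparison asks which epithelial transcripts depend on HIF2α in arthritic mice.

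Epas1 itself (ENSMUSG00000024140.10, GRCm38 chromosome 17, 86753700 to 86833410) was higher in the libraries labelled knockout. Its level was 34.0 ± 9.31 CPM (SD, n = 3) there and 16.3 ± 3.72 CPM (SD, n = 3) in the control libraries. The control libraries held 12.2, 19.4 and 17.5 CPM and the libraries labelled knockout 44.2, 25.9 and 31.9 CPM. The log2 fold change was 1.06 (SE 0.28, adjusted p = 0.0061, edgeR quasi-likelihood test). Correction for GC content and length gave 1.003 (SE 0.24, adjusted p = 0.014), a call that was lost without knockout library 1 (0.78, adjusted p = 0.067). An exact permutation test of the 6 values gave p = 0.10, two-sided, the smallest that 3 against 3 libraries allow. The targeted gene therefore goes against the label, and every direction here is that of the libraries labelled knockout against those labelled control. Counts per gene sum all exons, so reads from exons outside a deleted part count as well.

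Pigr, Sprr2a3, Cldn2, Cldn4 and Chgb are 5 genes that differed between the groups. Pigr, the receptor that carries immunoglobulin A across the epithelium, rose from 622 ± 137 to 3979 ± 101 CPM (SD, n = 3 each). Sprr2a3, a small proline-rich protein, fell from 517 ± 366 to 15.4 ± 5.99 CPM. Cldn2, a pore-forming tight junction protein, rose from 34.5 ± 14.2 to 154 ± 14.4 CPM, while the barrier claudin Cldn4 fell from 365 ± 32.1 to 79.0 ± 19.4 CPM. The secretory granule protein Chgb of enteroendocrine cells rose from 22.4 ± 11.2 to 143 ± 31.0 CPM. The groups did not overlap for any of these 5 genes, and each was called with and without correction for GC content and length and without each library in turn. The choice of genes to name used calls and, for some, groups that do not overlap, so this is no separate support. Among all tested genes, 72.6% had groups that did not overlap.

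**Figure D1:**
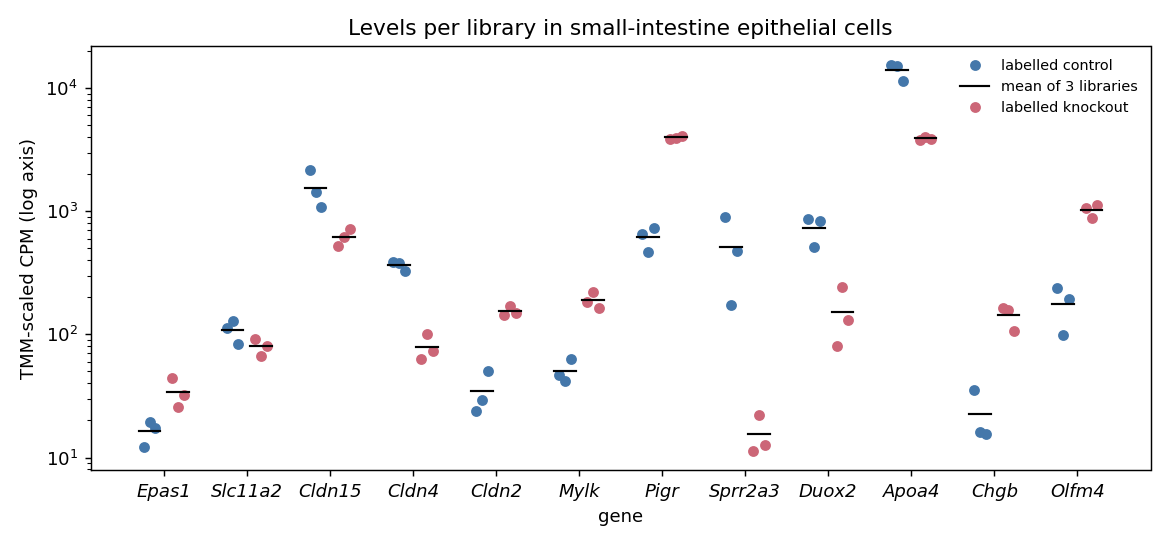
Level of 12 genes in each library, as TMM-scaled CPM on a log axis, with the control libraries in blue, the libraries labelled knockout in red and a black line at the mean of 3 libraries. Epas1 lies higher and Cldn15 lower in all 3 libraries labelled knockout, while the Slc11a2 values of the groups overlap.

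Across 15143 tested genes, 5636 were higher and 4499 lower in the libraries labelled knockout at an adjusted p below 0.05. The 3 values of each group did not overlap for 72.6% of the genes, where chance gives 10%. The fold changes followed transcript GC content: the decile of genes lowest in GC had a median log2 fold change of 1.604 and the highest decile one of -1.23. Across genes, which are not independent replicates, the Spearman correlation of fold change with GC was -0.74. Each library's own slope was 0.96, 0.93 and 0.44 log2 units per 10% GC in the control libraries and -0.79, -0.89 and -0.64 in those labelled knockout. With GC content and length corrected within each library, a step chosen after seeing the data, 2162 genes were higher and 2362 lower, of which 1871 and 1500 had the same call without it. Another 1099 genes were called only with the correction, and 54 were called in opposite directions with and without it. The corrected counts were 1164 and 1121 without knockout library 1, 1405 and 1440 without knockout library 2, and 1069 and 1549 without control library 2. Total count scaling gave 6550 higher and 2660 lower genes, and with each library's GC slope as a covariate edgeR called 0 genes (355 at an unadjusted p below 0.05). In all, 863 genes were higher and 511 lower with and without the correction and without each library in turn, and they are called retained in what follows. Corrected values are given beside each gene group.

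**Figure D2:**
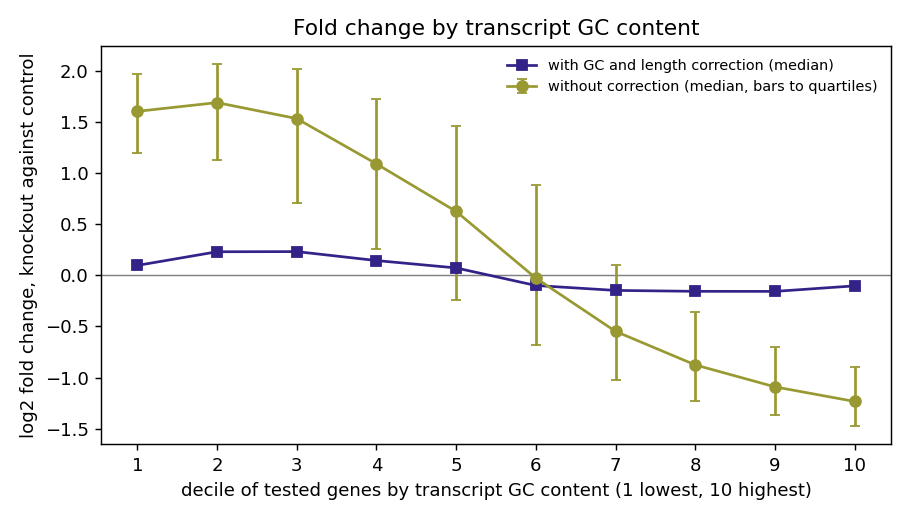
Median log2 fold change of the libraries labelled knockout against control in deciles of the tested genes ordered by transcript GC content, without correction (circles, bars to the quartiles) and with GC content and length corrected (squares). The uncorrected medians run from 1.604 in the lowest decile to -1.23 in the highest, and the corrected medians lie between 0.23 and -0.16.

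Among the 10 largest increases of genes that met the naming rule were the chemokine receptor Cxcr6 (log2 fold change 4.22, SE 0.92), Rgs1 (3.98), Sla (3.62), the interferon-induced GTPases Tgtp2 (3.83), Gbp2 (3.68) and Gbp4 (3.45), the receptors Cd200r2 (3.48) and Cd200r1 (3.45), and Ahrr (3.53, SE 0.61). Ahrr encodes the repressor of the aryl hydrocarbon receptor. Of these, Ahrr and Gbp2 were retained, with corrected changes of 3.49 (SE 0.61) and 2.76 (SE 0.60). Cxcr6, Cd200r2, Cd200r1 and Gbp4 missed the threshold after correction, with changes of 2.61 (SE 0.88), 2.19 (SE 0.76), 1.86 (SE 0.71) and 2.06 (SE 0.71) and adjusted p = 0.058, 0.063, 0.082 and 0.060, and each passed after correction without knockout library 3 (adjusted p = 0.0036, 0.0029, 0.0054 and 0.0023). Without knockout library 1 the corrected changes of Cxcr6, Cd200r2, Cd200r1 and Gbp4 were 1.74, 1.32, 1.02 and 1.65, none past the threshold. Knockout library 3 held 1.13 CPM of Cxcr6 against 18.6 and 10.5 CPM in the other 2 libraries labelled knockout. The retained genes were also lowest there. Ahrr was at 1.22 against 6.77 and 4.61 CPM, and Gbp2 at 2.37 against 12.1 and 12.7 CPM. Their control means were 0.36 and 0.70 CPM. The 5 increases with the smallest p were Pigr (2.68), the zinc transporter Slc30a5 (2.92), the mucosal chemokine Ccl28 (2.72), Fnbp4 (2.67) and Birc6 (2.50), all of them retained, with corrected changes of 2.42, 1.27, 1.10, 1.63 and 0.99.

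Among the 10 largest decreases were Sprr2a3 (-5.07, SE 0.64), the antimicrobial resistin-like protein Retnlb (-4.45, SE 0.52), the phospholipase Pla2g4c (-3.95, SE 0.86), the bile acid-induced hormone Fgf15 (-3.76, SE 0.98) and Duoxa2 (-3.49, SE 0.66). The others were Foxo6 (-2.79), the glycerol channel Aqp7 (-2.77), Rps27rt (-2.66), Tmem151a (-2.63) and Rpl28-ps1 (-2.61). Retained among them were Sprr2a3, Retnlb, Aqp7, Foxo6 and Rps27rt, with corrected changes of -6.48, -5.59, -3.37, -1.95 and -3.60. Pla2g4c was lost without knockout library 1 (-3.84, adjusted p = 0.068) or 2 (-3.80, adjusted p = 0.073), and Fgf15 without knockout library 1 (-3.31, adjusted p = 0.052) or 2 (-3.65, adjusted p = 0.12). The smallest p among the decreases belonged to Retnlb, Aqp7, Cldn4 (-2.21), the lipid droplet protein Cidec (-2.08, corrected -1.27) and Gprc5a (-2.33, corrected -1.86), all retained. Sprr2a3, Tgtp2, Rps27rt and Rpl28-ps1 have near-identical copies that can share reads, so their own levels are uncertain.

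Junction genes changed in both directions. Of 23 tested genes of the tight and adherens junctions, 13 rose and 6 fell, and 12 rose and 5 fell after correction, with medians of 0.95 and 0.75. Mylk, the myosin light chain kinase that contracts the junctional ring, rose by a log2 fold change of 1.91 (SE 0.24), Cldn2 by 2.16 (SE 0.29) and β-catenin, Ctnnb1, by 2.08 (SE 0.29), with corrected changes of 2.43, 1.74 and 2.07. Cldn4 had a corrected change of -1.38 (SE 0.20). Cldn15, a claudin that forms sodium pores, fell from 1558 ± 546 to 621 ± 100.3 CPM (log2 fold change -1.33, SE 0.28, adjusted p = 0.0016). Its corrected change was -0.91 (SE 0.26, adjusted p = 0.028), and this call was lost without control library 1 (-0.60), knockout library 1 (-0.79) or knockout library 2 (-0.90). The list did not pass camera without correction (adjusted p = 0.57) and passed with it (adjusted p = 0.041, but 0.92 with an estimated correlation), and not without control library 1 (0.061), control library 2 (0.076) or knockout library 3 (0.082). Its corrected increases numbered 7 without control library 2, and its corrected decreases 3 without control library 1, knockout library 1 or knockout library 2.

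Genes for iron handling showed no common direction. Of 14, 5 rose, 3 fell and 6 did not pass, and after correction 2 rose and none fell. Slc11a2, the apical iron importer and a known HIF2α target, held 79.9 ± 13.2 CPM against 108 ± 23.0 CPM in the control libraries (log2 fold change -0.44, SE 0.24, adjusted p = 0.12). Without control library 3 it passed, at -0.64 (adjusted p = 0.027), and the corrected value was -0.21 (SE 0.21). The ferritin chains Ftl1 (-1.63) and Fth1 (-1.05) and the folate and heme carrier Slc46a1 (-1.55) fell, and Ncoa4 (2.52), Flvcr1 (1.86), Heph (1.67), Tfrc (1.24) and Ireb2 (1.22) rose, all without correction. The Fth1 call was lost without control library 2 (-0.83, adjusted p = 0.054). After correction Heph was at -0.00, Tfrc at -0.06 and Ireb2 at -0.46, and those passing were Ncoa4 (1.38, adjusted p = 0.031) and Slc39a14 (0.98, adjusted p = 0.020). The exporter Slc40a1 (2.71, SE 1.58), the reductase Cybrd1 (0.73, SE 0.56), Hmox1 (-0.86, SE 0.43), Slc39a14 (0.31, SE 0.26) and Aco1 (0.62, SE 0.28) did not pass. Leaving out control library 2 brought Slc40a1 to 4.73, knockout library 2 brought Cybrd1 to 1.16, control library 1 brought Hmox1 to -1.10 and control library 3 brought Aco1 to 0.93, each then past the threshold. No iron gene was retained.

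Of 33 hypoxia and glycolysis genes, 6 rose and 18 fell, and 6 rose and 9 fell after correction, with medians of -0.64 and -0.11. The lactate exporter Slc16a3 fell by 1.96 on the log2 scale (SE 0.24, corrected -0.88) and was retained. Gapdh (-1.68) and Aldoa (-1.67) fell and the histone demethylase Kdm3a rose (2.09), with corrected values of -0.73, -0.67 and 0.82. The list missed the threshold in camera (adjusted p = 0.058, and 0.45 after correction), and without correction it passed without control library 1 (0.0073) or 2 (0.041).

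Nuclear genes of oxidative phosphorylation formed the list with the smallest camera p. Of 40 members, 3 rose and 28 fell (median -1.05, adjusted p = 4.8e-05, but 0.98 with an estimated correlation), and 3 rose and 27 fell after correction (median -0.91, adjusted p = 1.7e-11, but 0.92 with an estimated correlation). Uqcrq, a subunit of complex III, fell by 1.68 on the log2 scale (SE 0.26, corrected -1.11) and Atp5d of the ATP synthase by 1.81 (SE 0.26, corrected -0.61), while Sdha of complex II rose by 1.94 (SE 0.27, corrected 1.68). In all, 10 members were retained as lower and 1 as higher. The dissociation and heat shock list was the other that passed without correction, with 3 of 20 members higher and 14 lower (median -1.24, adjusted p = 0.0080, and 0.98 with an estimated correlation). After correction none rose and 9 fell (median -0.60, adjusted p = 0.012, and 0.92 with an estimated correlation), and without knockout library 3 the corrected list missed the threshold (adjusted p = 0.079). Its corrected decreases numbered 5 without knockout library 1, and its median was -0.92 without knockout library 2. Zfp36, which destabilises cytokine mRNAs, fell by 1.63 on the log2 scale (SE 0.22, corrected -1.20) and Junb by 1.82 (SE 0.26, corrected -0.61).

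Fat absorption genes fell more often than they rose: 5 of 23 rose and 12 fell, and 1 rose and 10 fell after correction (medians -1.02 and -0.59). Apoa4, an apolipoprotein of chylomicrons, fell from 14013 ± 2144 to 3908 ± 116 CPM, with Apoc3 (-1.97) and the transcription factor Creb3l3 (-1.80) lower and the acyl-CoA synthetase Acsl5 (2.20) higher. All 4 were retained, with corrected changes of -0.93, -0.83, -0.86 and 1.25. With all libraries the list passed camera only after correction (adjusted p = 0.058 and 0.026, but 0.92 with an estimated correlation), and without correction also without control library 1 (0.011) or 2 (0.042). Without knockout library 1 its corrected decreases numbered 5. Of 26 genes of fatty acid oxidation, 12 rose and 8 fell, and 2 rose and 7 fell after correction. Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 1.70 (corrected 2.10) and Acadm by 2.17 (corrected 1.75). These were the 2 members retained as higher, and 1 other was retained as lower. Cholesterol synthesis had 10 of 24 genes higher and 11 lower (3 and 5 corrected). Fatty acid synthesis had 8 of 15 higher and 4 lower (5 and 3 corrected), with Gpam at 1.79 (corrected 1.29) and Elovl1 at -1.38 (corrected -1.10), both retained. Ceramide metabolism had 10 of 24 higher and 7 lower (3 and 7 corrected), with Degs2 at -1.59 (corrected -0.93) and retained. None of these last 4 lists passed camera (adjusted p = 0.97 each without correction, and 0.78, 0.78, 0.37 and 0.21 with it).

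In the antimicrobial list of enterocytes, Pigr was the 1 member of 17 that rose, and 5 fell, or 6 after correction (medians -0.31 and -0.79). Besides Sprr2a3 and Retnlb, the hydrogen peroxide-producing oxidase Duox2 fell from 736 ± 195 to 152 ± 83.9 CPM and was retained (corrected -2.08). Its maturation factor Duoxa2 fell from 338 ± 175 to 30.2 ± 24.3 CPM, with a corrected change of -2.99 (SE 0.64). With all libraries the list passed camera only after correction (adjusted p = 0.22 and 0.038, but 0.92 with an estimated correlation), and not without knockout library 1 (0.13), knockout library 3 (0.066) or control library 3 (0.073). Its uncorrected median was -0.05 without knockout library 1 and -0.97 without knockout library 2, where it passed (adjusted p = 0.011), and its corrected median -0.38, with 3 members lower, and -1.35 in this order. Of 21 cytokines and chemokines, 8 rose and 3 fell (2 and 6 corrected), with Ccl28 higher and Cxcl16, the ligand of Cxcr6, lower (-1.56, corrected -2.28), both retained. Of 31 interferon response genes, 18 rose and 5 fell (7 and 2 corrected), with Irgm1 at 2.83 (corrected 1.36, retained). Of 10 genes of MHC class II presentation, 1 rose and 2 fell, and none passed after correction. These last 3 lists had adjusted p = 0.97, 0.29 and 0.47 in camera and did not pass after correction. Without knockout library 3 the uncorrected interferon list passed camera (median 1.90, adjusted p = 0.0078, against a median of 1.58 with all libraries). Without knockout library 2 the uncorrected interferon median was 1.01 (camera adjusted p = 0.56).

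**Figure D3:**
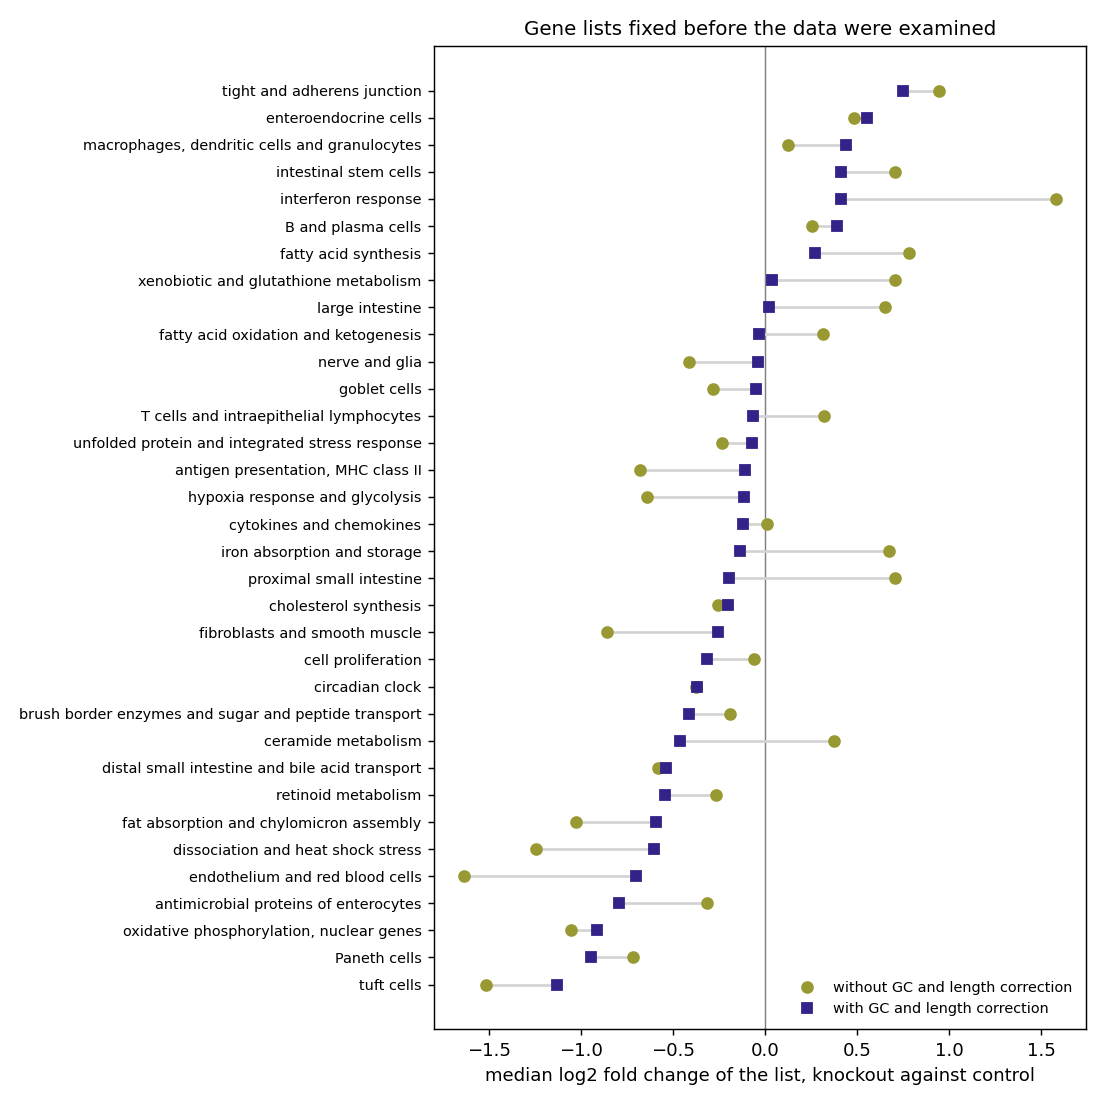
Median log2 fold change of the tested members of 34 gene lists in the libraries labelled knockout against control, without correction (circles) and with GC content and length corrected (squares). The tight and adherens junction list has the highest corrected median, 0.75, and the tuft cell list the lowest, -1.13.

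Markers of epithelial cell types did not move together. Of 22 enteroendocrine genes, 9 rose and 6 fell, and 10 rose and none fell after correction (medians 0.48 and 0.55). Their uncorrected median was 0.30 without knockout library 2. Chgb rose by 2.68 (SE 0.35, corrected 2.93, retained), with the transcription factor Neurod1 at 2.64 (corrected 1.04) and the serotonin-synthesis enzyme Tph1 at 2.42 (corrected 1.184). The list passed camera after correction (adjusted p = 0.023, and 0.92 with an estimated correlation), but not without control library 3 (0.073), and its 10 corrected increases numbered 5 without knockout library 1 and 6 without control library 2. Of 18 Paneth cell genes, none rose and 3 fell, or 4 after correction (medians -0.71 and -0.94). The uncorrected median was -0.47 without control library 1, -0.37 without knockout library 2 and -1.33 without knockout library 3, where the list passed (adjusted p = 0.00083). The corrected count lower was 15 without knockout library 3 (median -1.55), 2 without knockout library 2 (-0.54) or control library 2 (-1.07), 1 without control library 3 (-1.16) and 0 without control library 1 (-0.57) or knockout library 1 (-0.85). Of these, the defensins Defa3 (-1.59, corrected -1.89) and Defa17 (-1.39, corrected -1.61) belong to a family with near-identical members, and the Defa17 call was lost without control library 1 (-1.12, adjusted p = 0.051). The Paneth list passed after correction (adjusted p = 0.027, and 0.92 with an estimated correlation), but not without control library 1 (0.094), knockout library 2 (0.098) or control library 3 (0.054). Of 16 stem cell genes, 8 rose and 1 fell (5 and 1 corrected), with Olfm4 at 2.53, Lgr5 at 2.51 and Cd44 at 1.86, and corrected values of 1.32, 1.30 and 0.93. Of these 3 genes Cd44 was retained. Of 19 goblet cell genes, 5 rose and 7 fell (4 and 3 corrected), with Rep15 at 2.31 (corrected 0.98). Of 18 tuft cell genes, 2 rose and 4 fell, and none passed after correction. Of 30 proliferation genes, 9 rose and 10 fell (3 and 8 corrected), with the replication helicase genes Mcm4 at 2.62 (corrected 1.46) and Mcm6 at 2.44 (corrected 1.22) retained as higher. In all, 3 proliferation genes were retained as higher and 1 as lower. With all libraries, the stem, goblet, tuft and proliferation lists did not pass camera with or without the correction. Without control library 1 the uncorrected tuft list passed (median -1.99, adjusted p = 2.7e-05), against a median of -1.51 with all libraries and -0.89 without control library 2.

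Genes of brush border enzymes and transporters numbered 9 higher and 7 lower of 26, and 2 higher and 11 lower after correction, with the sodium-proton exchanger Slc9a3 at 1.39 (corrected 1.46, retained). Slc9a3 was the 1 brush border gene retained as higher, and 2 were retained as lower. Of 14 proximal intestine genes, 5 rose and 3 fell (0 and 3 corrected). Of 14 distal intestine and bile acid genes, 5 rose and 7 fell (0 and 5 corrected), among them the nuclear receptor Nr0b2 (-2.43, corrected -1.40) and the guanylin gene Guca2a (-1.83, corrected -0.90). Without control library 1 the corrected changes of Nr0b2 and Guca2a were -0.91 and -0.58. Both corrected calls were lost there and without knockout library 1 or 2, and that of Guca2a also without control library 3. Of 10 large intestine genes, 4 rose and 1 fell (1 and 1 corrected). Of 10 retinoid genes, 2 rose and 2 fell (1 and 3 corrected), with Aldh1a1, which makes retinoic acid, retained as higher at 2.70 (corrected 1.42). Of 29 xenobiotic and glutathione genes, 13 rose and 6 fell (3 and 6 corrected), with Nfe2l2 at 2.16 (corrected 0.73) and the glutathione-synthesis gene Gclc at 2.44 (corrected 2.07), both retained. They were the 2 xenobiotic and glutathione genes retained as higher, and 1 was retained as lower. Of 20 unfolded protein and integrated stress genes, 6 rose and 7 fell (3 and 3 corrected), with the endoplasmic reticulum chaperone Hspa5 at 2.69 (corrected 1.63, retained) and Trib3 at -2.28 (corrected -1.06). Of 17 clock genes, 5 rose and 6 fell (2 and 4 corrected), and Per1 fell (-1.87, corrected -1.08) while Per2 rose (1.19, corrected 1.71), both retained. None of these lists passed camera, with or without correction.

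Markers of other cell types were measured for RNA from outside the epithelium. Of 24 T cell and intraepithelial lymphocyte genes, 2 rose and none fell (1 and 1 corrected), with Itgae, the integrin chain of intraepithelial lymphocytes, at 2.63 (SE 0.60, corrected 2.14). None of the 17 B and plasma cell genes rose and 1 fell (none corrected). Of 19 genes of macrophages, dendritic cells and granulocytes, 5 rose and 1 fell (1 and 0 corrected), with the macrophage gene Adgre1 retained, from 0.062 ± 0.026 to 0.79 ± 0.37 CPM (log2 fold change 3.56, corrected 2.59). Of 14 fibroblast and smooth muscle genes, 1 rose and 5 fell (0 and 2 corrected), including the actin-severing protein Gsn (-2.08, corrected -1.15). Of 13 endothelial and red blood cell genes, 3 rose and 8 fell (3 and 3 corrected). Lyve1 (2.70, corrected 1.78) and Prox1 (2.33, corrected 2.01), placed on this list as endothelial genes, rose. The globin gene Hbb-bt fell (-1.98, corrected -2.21). All were retained, and Lyve1 and Prox1 had mean levels under 4 CPM. Which cells these transcripts came from was not tested. Of 6 nerve and glia genes, 1 rose (1 fell corrected). None of these lists passed camera, and 4 exocrine pancreas and 2 adipocyte genes were measured, too few to test. Adjusted over the list alone, the uncorrected counts of all 34 lists moved by at most 1 gene in each direction, except for MHC class II (0 higher, 0 lower), proximal intestine (3 and 3) and T cells (0 and 0). Without correction, the direction of camera opposed the sign of the median in the fatty acid oxidation, proximal intestine, T cell and B cell lists, and the mean opposed the median in the cholesterol, brush border, unfolded protein and proliferation lists. No list passed camera with an estimated correlation, with or without the correction.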

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

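The GC and total count alternatives were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers shared by the groups. Counts of higher and lower genes stayed within 1.5 times of 5636 and 4499 under all alternatives fixed before the data were examined, but not under the added ones. They were 2162 and 2362 with the GC content and length correction, 2250 and 2411 with the GC correction alone, and 0 and 0 with the GC slope as a covariate in edgeR (355 at an unadjusted p below 0.05), where the slope nearly repeats the group (variance inflation 18.9). Total count scaling gave 6550 and 2660. Leaving out 1 library gave 4875 to 5794 higher and 3618 to 4745 lower, and after correction 1069 to 2025 higher and 1121 to 2290 lower, with fewer samples in each. The share of calls that were higher was 55.6% as reported and 71.1% with total count scaling, and the median fold change shifted from the reported one by 0.48 with total counts, -0.15 with DESeq2 size factors, -0.12 with the DESeq2 Wald test and -0.33 with the correction. Epas1 stayed between 0.83 and 1.53 and past the threshold except with the covariate (0.75, adjusted p = 0.9999) and, with the GC content and length correction, without knockout library 1 (0.78, adjusted p = 0.067). With that covariate, 24 of the 94 named genes changed sign and 0 passed. Lists passing camera numbered 2 as reported and 0 with an estimated correlation. They numbered 7 with the GC content and length correction, 8 with the GC correction alone and 2 to 5 without 1 library. By fry, 5 lists passed without correction and 0 with the GC content and length correction. Of the 2 reported lists, oxidative phosphorylation passed fry without correction (adjusted p = 0.017) and the dissociation and heat shock list did not (adjusted p = 0.054). The cause was not tested.

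Named genes that changed sign had missed the threshold before or missed it after the change. Slc11a2 was 0.0603 with total counts. With the GC content and length correction, Cybrd1 was -0.78, Heph -0.0013, Tfrc -0.0555 and Ireb2 -0.46, and with the GC correction alone Cybrd1 was -0.46, Tfrc -0.22, Aco1 -0.11 and Ireb2 -0.22. List medians that changed sign, none past the threshold, were with the 2 corrections in this order: iron -0.13 and -0.22, cytokines -0.12 and -0.34, fatty acid oxidation -0.0327 and -0.0237, ceramide -0.46 and -0.48, proximal intestine -0.20 and -0.11, and T cells -0.0665 and -0.22. The goblet cell median was 0.0181 with the GC correction alone, the cytokine median -0.16 with DESeq2 size factors and the macrophage median -0.00255 with the stricter filter. Without 1 library, list medians near 0 ran from -0.00192 to 0.104 for cytokines, -0.322 to 0.149 for the brush border, -0.258 to 0.0106 for proliferation, -0.190 to 0.727 for T cells, -0.138 to 0.923 for B cells and -0.137 to 0.531 for macrophages. With 3 libraries a group and no GC trend, the uncorrected fit found 21% of simulated 2-fold changes. Changes of that size or smaller can therefore be missed. In the real data without correction, 5144 of 5636 higher and 3231 of 4499 lower calls were at least 2-fold. The remaining calls were smaller, so the simulated share sets no lower limit for the real data.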

Other observations

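Groups of genes chosen after their values were seen were counted but not tested as lists. Of 82 cytosolic ribosomal protein genes, 7 were higher and 56 lower in the libraries labelled knockout (median log2 fold change -1.03), and 4 and 39 after correction (median -0.63). Of 32 histone genes, 1 was higher and 13 lower (1 and 11 corrected). Of 286 processed pseudogenes, 51 were higher and 137 lower (17 and 79 corrected), and reads shared with their parent genes enter these counts. Of 367 genes of long intergenic noncoding RNA, 103 were higher and 49 lower (median 0.29), but 15 and 74 after correction (median -0.31), a reversed balance. Of 71 immunoglobulin genes, 2 were higher and none lower (1 and 0 corrected), and 5 genes of mast cells held no call.

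Which genes of the sex chromosomes were present gave a pattern that cuts across the groups, but their levels did not. Xist was at 51.9 CPM in control library 1 and 172 CPM in knockout library 3, with Eif2s3y at 0 CPM in both. Xist was at 0.32 CPM in control library 2 and at 0.44 CPM in knockout libraries 1 and 2, with Eif2s3y at 3.58, 17.5 and 19.5 CPM. Control library 3 held both, with Xist at 48.4 CPM and Eif2s3y at 5.21 CPM. The Y-linked gene Kdm5d was at 4.06 CPM in control library 2 and at 21.1 and 23.6 CPM in knockout libraries 1 and 2. Between libraries alike in sex, Xist, Eif2s3y and Kdm5d were thus higher in those labelled knockout, and the cause was not tested. Sex was not a term in the fits.

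Of the tests in what follows, those of GC content within groups, of the share of calls kept, of Epas1 and of enterocyte share were chosen only after the results were seen. Fold changes followed GC content. Without the 20 most abundant genes the correlation across genes was still -0.74. This does not decide whether those genes contributed, because rescaling the libraries shifts all fold changes nearly alike and leaves their ranks. Libraries of one group also differed along GC content, with an absolute Spearman correlation of at least 0.2 in 4 of the 6 pairs within groups (0.046 to 0.55, with 2 of the 4 close to that bound at 0.206 and 0.231, and 4 the number asked for) against 0.64 to 0.75 in the 9 pairs between groups, so library preparation may have contributed. Of the called genes, 33.3% kept call and direction after the trend was removed. This does not decide whether the trend was the whole cause, because the correction used medians over annotated transcripts. A gene whose expressed transcript differs from that median can keep a call. A biological difference between the genotypes stays open and untested against the preparation, since both follow the groups.

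Of the 10 splits of the 6 libraries, 1 called as many genes, the real one with 10135, or 4524 after correction, and the highest other called 1 in both, but 10 splits are too few for a share under 0.05. All 10 splits had at least as many lists passing camera as the 2 of the real one, up to 11, and after correction as the 7 of the real one, up to 12. The list calls in the report are thus no more than other groupings of these libraries gave. Neither a structure of the samples nor a correlation within lists above the preset 0.01 was tested as the reason, and 0 lists passed with an estimated correlation.

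Epas1 was higher in the libraries labelled knockout. The median GC content and length of its annotated transcripts are argued against as its cause, since the corrected log2 fold change was 1.003 (SE 0.24). Whether RNA from endothelial cells, where Epas1 is abundant, adds to it is open. The 8 endothelial markers had a corrected median of 0.52 (SE 0.56), with 3 called higher and 1 lower. With a median level of 1.71 CPM they are too low to decide. Exchanged group labels cannot be told apart from correct ones by Slc11a2, whose corrected change was -0.21 (SE 0.21). Leaving out 1 library gave corrected Slc11a2 changes from -0.09 to -0.39, none past the threshold. Counts per exon, which would show whether the deleted part is read, were not analysed here, and the +/- in both genotype labels leaves open how many alleles were targeted.

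The oxidative phosphorylation list had a lower median, a call lost with an estimated correlation (adjusted p = 0.98, and 0.92 corrected). Its uncorrected median of -1.05 lay at the 0.34th percentile of 10000 random lists matched on GC content, length and level. The medians of the random lists centred on -0.57. This does not decide whether these properties were the whole cause. The list matched was the one with the smallest camera p, a choice for which the percentile does not allow. Random lists also do not carry any correlation among the members. Cytosolic ribosomal protein genes fell as well, with a median of -1.03 (-0.63 corrected). A lower share of absorptive enterocytes would raise the markers of other epithelial types alike, but the enteroendocrine minus Paneth mean differed between the groups by 1.72 on the log2 scale, 2.09 pooled SDs, with no overlap between libraries. This does not decide the question, since the score holds no enterocyte markers and a change in Paneth cells alone would move it. The Paneth mean by itself overlapped between the groups. It was 8.37 in knockout library 3, within the 8.23 to 8.82 of the control libraries, and 7.32 and 6.34 in knockout libraries 1 and 2. After correction enterocyte genes fell more often: 2 rose and 11 fell of 26 for the brush border. For fat absorption 1 rose and 10 fell of 23. Without correction these counts were 9 and 7, and 5 and 12. The bound of 2 pooled SDs was also narrowly passed. It was set when this score replaced a permutation test over marker genes. That test treated them as independent, and its result, pointing the same way, had been seen. A change in the mitochondrial genes of the epithelium that follows the genotype is a hypothesis left open, untested against a difference in library preparation, since both follow the groups.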
